A study of Mus musculus with 7 samples.

How the data were processed

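Small RNA was sequenced from the lateral ventricles and choroid plexus of adult C57BL/6J mice, in 4 libraries from TAp73 knockouts and 3 from wild types. TAp73 is the form of the transcription factor p73 that carries a transactivation domain, and it is encoded by Trp73. Per the labels' protocols, total RNA was isolated with phenol and chloroform and the libraries were made with the Illumina TruSeq small RNA kit. The submitters' processing notes name bcl2fastq 2.17.1.14, DESeq2 and the mouse build mm10 without saying what each was used for. The aligner, the counting tool and the annotation of small RNAs are not given in the sources used here. The kit carries no molecular identifiers, so reads are not independent molecules, and the detection limits given with the results cover counting error only. The intervals given with fold changes come from the edgeR fit described below and include the spread between libraries.

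The values deposited by the authors are raw counts of reads per named small RNA, not normalized, with whole numbers in each library. Each table has 66573 rows, of which 5 are closing lines for unassigned reads, and these lines hold 0 reads in every library. The share of unaligned or ambiguous reads therefore cannot be read from these tables, and the total per library is the total of assigned reads. Of the named rows, 1914 are mature mouse miRNAs, 21684 are miRNAs of other species, 39972 are mouse piRNAs, and the remainder are mouse snoRNAs, rRNA genes, predicted miRNAs and other small RNA genes. Mouse miRNA rows held 98.85% of all reads. In 12 mouse rows several mature miRNAs of identical sequence share a joined name, such as the 5p arms of miR-486a and miR-486b. How reads of near-identical family members, such as those of let-7, were split between rows is not stated, so their separate values are less certain than family totals.

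Groups were taken from the genotype in the labels. The labels do not say outright that each library came from a separate animal, so the p-values measure the spread between these libraries. No batch is given. The libraries were compared pair by pair with a chi-square test over miRNAs with at least 20 reads in the pair. No pair was identical, and the chi-square per degree of freedom ran from 46.6 to 271.2, so no library was counted as a repeat of another. Over mouse miRNAs, wild type replicate 2 had log2-scale Pearson correlations of 0.993, 0.994 and 0.993 with knockout replicates 1, 2 and 4. Those with wild type replicates 1 and 3 were lower, at 0.991 each, and that with knockout replicate 3 was 0.988. This library was thus not closest to its own genotype. Because only small RNA was measured, Trp73 itself was not measured, and the knockout labels were not checked against the targeted gene.

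Mouse miRNA rows were tested with edgeR 4.0.16 in R 4.3.3, with TMM scaling, the filterByExpr filter by group (minimum count 10, minimum total 15), robust dispersion estimates and the quasi-likelihood test. P-values were adjusted by the Benjamini-Hochberg method and called under 0.05. Levels are given as counts per 1000000 mouse miRNA reads with TMM scaling (CPM), as mean ± SD, and log2 fold changes are knockout minus wild type with their standard error. The summed level of each of the miR-449 and miR-34b/c clusters was compared on the log2 scale with an exact permutation test over all 35 splits of 4 against 3 libraries, two-sided on the absolute difference of means. The smallest p this design allows is 0.029. Depth and the share of mouse miRNA reads were compared in the same way. Fixed miRNA lists were tested with camera in limma 3.58.1 at its preset correlation of 0.01, two-sided, with adjustment over the 20 lists that had at least 2 tested members. Some lists share members, for example miR-375 in the other epithelia and pituitary lists, and miR-223, miR-155 and miR-146a in the leukocyte and inflammation lists.

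The test and its design, the lists and the rule for naming miRNAs were fixed before the data were examined. Named are each tested arm of the miR-34 and miR-449 family, the 10 largest increases and 10 largest decreases among called miRNAs, the 5 smallest p-values in a direction with fewer than 5 calls, 2 to 4 tested members with the smallest p of each list described, and the 5 most abundant miRNAs. The alternatives fixed at the same time were DESeq2 1.42.0, limma-voom, no robust estimation, 3 other scalings, no filter, a stricter filter of 10 CPM in at least 3 libraries, rows of all species summed by name, the 4 libraries with consecutive title numbers, a covariate made of the miR-204 and miR-211 levels, camera with an estimated correlation, the fry rotation test, an edgeR test of each cluster sum, and leaving out each library in turn. Chosen after seeing the data were the omission of knockout replicate 3 and wild type replicate 2 together, thinning of every library to the reads of the shallowest, sets of miRNAs that share a host gene, ratios to miR-204-5p, the shares of the other RNA classes, a test of the small RNAs other than mouse miRNAs, and the covariate with 1 library left out at a time. For the Htr2c set with the covariate, the bound on the median and the preset camera p were written before the result, but it was read as met until other readings had been tried. Those were an unadjusted and then an adjusted p with an estimated correlation, before the spread over left-out libraries, used here, was added with the median known. Also adopted after the values were seen were the reading of the let-7 scalings by the gap to all tested miRNAs, and the rule that a camera p at the preset correlation cannot exclude chance where at least 0.05 of the splits give as small a p. Depth for let-7 and a single library for the Htr2c set are judged by the medians together with the bounds written before, which were met.

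The tests were checked on simulated data of the same 7 libraries, with 10 runs and 546 miRNAs tested per run. Among the changed miRNAs that passed the filter, they recovered 67.5% of those changed 2-fold, 97.7% of those changed 4-fold and 100% of those changed 8-fold. Of the calls, 3.76% were false. Changed miRNAs that the filter removed are not in these percentages. Counts were drawn independently for each miRNA from dispersions estimated from these data, so structure shared between miRNAs within a library was not simulated and the percentages do not cover it. Positions are from GENCODE release 21 for mouse, on build GRCm38, which is mm10, and mature names were matched to hairpin genes by name. Python 3.11.15, pandas 2.3.3 and numpy 2.4.6 were used to read the tables.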

Results

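Small RNA libraries from the lateral ventricles and choroid plexus of adult mice were compared between 4 TAp73 knockouts and 3 wild types. The ventricle walls carry ependymal cells with many motile cilia, and the choroid plexus is the epithelium that secretes cerebrospinal fluid. The series title places the comparison in the study of how TAp73 acts on posttranscriptional regulation during the formation of multiciliated cells in the brain. Knockout replicates 1 to 4 had 9343921, 7775966, 969106 and 3925927 assigned reads, and wild type replicates 1 to 3 had 2727175, 2238917 and 3692879. The totals did not differ beyond the spread between libraries (exact permutation p = 0.34, two-sided). Mouse miRNAs took 98.8% ± 0.18 of the reads in knockouts (SD, n = 4) and 98.8% ± 0.088 in wild types (SD, n = 3; exact permutation p = 0.89). Knockout replicate 3 was the shallowest library, where the 3 reads that a count of 0 allows correspond to 3.14 CPM, against 0.325 CPM in knockout replicate 1.

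The knockout libraries held more of the miR-449 cluster and less of the miR-34b/c cluster, which belong to one miRNA family with a shared seed that is abundant in multiciliated cells. miR-449c-5p was 8.70-fold higher (95% interval 4.66 to 16.2), at 17.9 ± 5.76 CPM in knockouts (SD, n = 4) and 2.14 ± 1.25 CPM in wild types (SD, n = 3). miR-449a-5p was 6.34-fold higher (3.39 to 11.9), at 132.7 ± 63.6 against 21.6 ± 5.24 CPM. The most abundant arm of the other branch, miR-34c-5p, was 5.27-fold lower (3.14 to 8.84), at 462.9 ± 112.6 CPM in knockouts and 2447 ± 1122 CPM in wild types. These arms and the other 3 tested arms of miR-34b and miR-34c were the 6 miRNAs called among 534 tested, with 2 higher and 4 lower.

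In edgeR's quasi-likelihood test, miR-449c-5p rose by 3.12 ± 0.41 on the log2 scale (log2 fold change ± SE, adjusted p = 0.0018) and miR-449a-5p by 2.67 ± 0.41 (adjusted p = 0.0048). miR-34b-3p changed by -2.56 ± 0.29 (adjusted p = 0.0014), miR-34b-5p by -2.40 ± 0.32 (adjusted p = 0.0018), miR-34c-5p by -2.40 ± 0.33 (adjusted p = 0.0048) and miR-34c-3p by -2.51 ± 0.47 (adjusted p = 0.019). For each of the 6 arms, the 4 knockout libraries lay on one side of the 3 wild type libraries. At the third locus of the family, miR-34a-5p was not called: it stood at 96.5 ± 23.2 CPM in knockouts and 80.6 ± 26.8 CPM in wild types, a log2 fold change of 0.26 ± 0.26 with a 95% interval of -0.30 to 0.82 (edgeR adjusted p = 0.71). miR-449b had 0 reads in all 7 libraries, and miR-449a-3p, miR-449c-3p and miR-34a-3p had 1, 2 and 7 reads in total and were not tested. Counts behind the weakest arms were low: miR-449c-5p had 2, 7 and 10 reads in the wild types, and miR-34c-3p had 0 reads in knockout replicate 3.

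**Figure D1:**
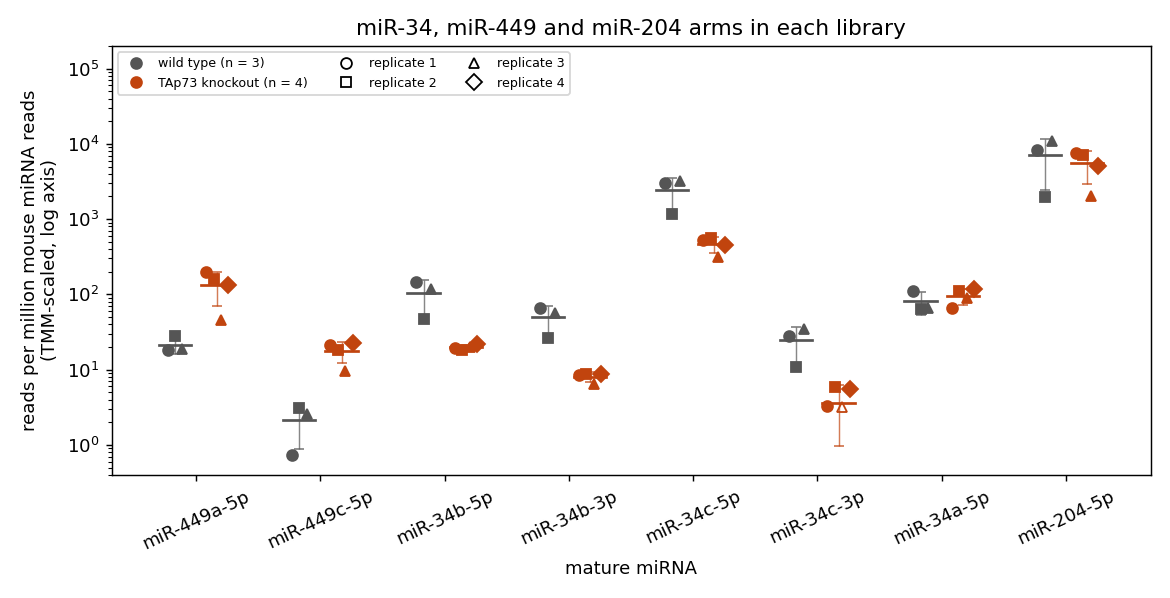
Level of each tested miR-34 and miR-449 arm, and of miR-204-5p, in every library, in CPM (reads per 1000000 mouse miRNA reads, TMM-scaled) on a log axis. Each point is 1 library, marker shapes give the replicate, horizontal lines with error bars are group means ± SD, and the open marker is the library with 0 reads, drawn at its limit of 3 reads. The 4 knockout points for miR-449a-5p run from 45.8 to 195.6 CPM, above the wild type points of 18.4 to 27.6 CPM, while for miR-34c-5p they run from 310.1 to 565.2 CPM, below the wild type points of 1157 to 3198 CPM.

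The 2 clusters lie on different chromosomes (build GRCm38, GENCODE release 21). Mir449a (chromosome 13, 113037534 to 113037624, plus strand), Mir449b (113037419 to 113037498) and Mir449c (113035983 to 113036091) lie in introns of the protein-coding gene Cdc20b on its own strand. Mir34b (chromosome 9, 51103562 to 51103645, minus strand) and Mir34c (51103034 to 51103110, minus strand) lie within an intron of Btg4, which is transcribed from the other strand. Mir34a (chromosome 4, 150068454 to 150068555, plus strand) lies in no other annotated gene, on the chromosome that also carries Trp73 (154056253 to 154140208).

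Summed over its arms, the miR-449 cluster stood at 150.8 ± 68.1 CPM in knockouts (SD, n = 4) and 23.7 ± 6.18 CPM in wild types (SD, n = 3), a log2 difference of 2.54 ± 0.48 or 5.82-fold. Each knockout library lay above each wild type library, but the exact permutation test did not pass (p = 0.057, two-sided), because grouping knockout replicate 3, at 56.5 CPM, with the wild types gave an absolute difference of 2.64. The planned edgeR test of the same sum did pass, with a log2 fold change of 2.71 (adjusted p = 0.0034). The miR-34b/c cluster stood at 494.5 ± 114.9 CPM in knockouts and 2625 ± 1202 CPM in wild types, a log2 difference of -2.31 ± 0.51, 4.94-fold lower (exact permutation p = 0.029, the smallest possible). Beside these clusters, miR-204-5p, which is abundant in choroid plexus, varied widely within both groups: it was lowest in wild type replicate 2 at 1979 CPM and knockout replicate 3 at 2042 CPM, and 5111 to 10980 CPM in the other 5. The group means of miR-204-5p, 5502 ± 2560 CPM in knockouts (SD, n = 4) and 7072 ± 4616 CPM in wild types (SD, n = 3), did not differ beyond this spread (exact permutation p = 0.69).

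The number of called miRNAs depended on single libraries. It was 3 without wild type replicate 1 (1 higher, 2 lower) and 14 without wild type replicate 2 (6 higher, 8 lower), while without knockout replicate 1 the lower calls numbered 2, and without wild type replicate 3 the higher calls numbered 1. miR-449a-5p lost its call without wild type replicate 1 (edgeR adjusted p = 0.11) or replicate 3 (0.051). miR-34c-5p lost it without wild type replicate 1 (0.069) or knockout replicate 1 (0.064), and miR-34c-3p lost it without each library in turn except knockout replicate 3 and wild type replicate 2 (up to 0.16). By contrast, miR-449c-5p, miR-34b-3p and miR-34b-5p were called in each of the 20 alternatives tried.

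Beyond this family, no miRNA passed the adjusted threshold in the edgeR test. Of the 534 tested, 69 (12.9%) had an unadjusted p under 0.05, and 59 (11.05%) had groups that did not overlap, against 5.71% by chance. The smallest p-values in the higher direction after miR-449 belonged to let-7f-5p (log2 fold change 0.50 ± 0.12, adjusted p = 0.10), let-7c-5p (0.47 ± 0.12, adjusted p = 0.10) and let-7a-5p (0.46 ± 0.12, adjusted p = 0.13). In the lower direction the next was miR-3547-3p (-1.62 ± 0.38, adjusted p = 0.094). DESeq2 called 14 miRNAs on the same counts, among them these 4. It gave no adjusted p for 94 of the 534, so it adjusted over fewer miRNAs than edgeR. The 5 most abundant miRNAs were miR-127-3p at 19.2% ± 1.90 of mouse miRNA reads (SD, n = 7), miR-181a-5p at 11.4% ± 0.96, miR-99b-5p at 6.54% ± 0.89, miR-26a-5p at 5.61% ± 0.54 and miR-125b-5p at 3.79% ± 0.32. Their log2 fold changes lay between -0.16 for miR-127-3p and 0.25 for miR-125b-5p, and none passed (smallest edgeR adjusted p = 0.38).

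**Figure D2:**
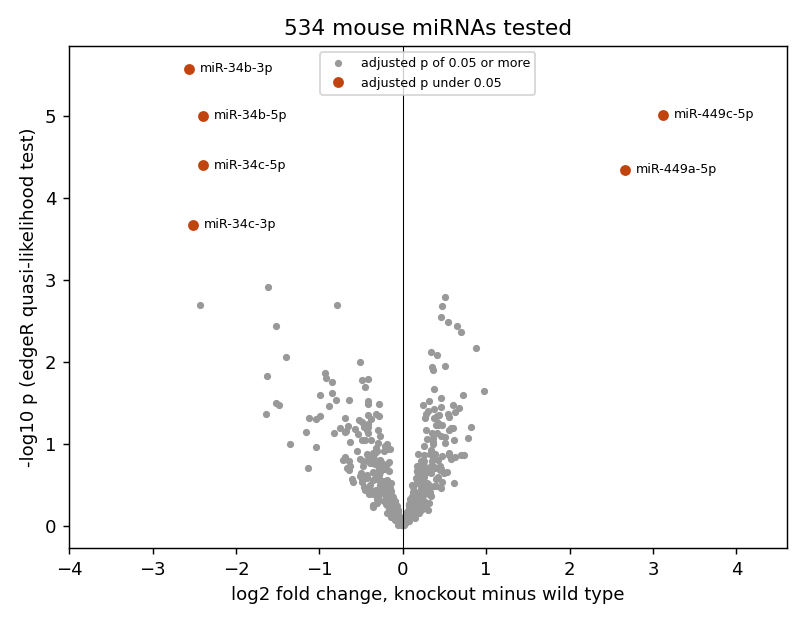
Log2 fold change (knockout minus wild type, horizontal axis) against the -log10 p of edgeR's quasi-likelihood test (vertical axis) for the 534 tested mouse miRNAs. Each point is 1 miRNA, and the 6 with an adjusted p under 0.05 are named, with 2 higher and 4 lower.

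Among the 20 fixed lists tested with limma's camera, 3 passed. The miR-449 cluster (2 of 2 tested members rose, log2 fold changes 2.67 and 3.12) had an adjusted p of 4.0e-11, and the miR-34b/c cluster (4 of 4 fell, median -2.45) had an adjusted p of 3.0e-20. Both held with an estimated correlation (adjusted p = 0.034 for each). The third was let-7, a large and broadly expressed family of differentiated tissues, with a median log2 fold change of 0.20 and 13 of 20 tested members positive (adjusted p = 0.030, and 0.22 with an estimated correlation). Its 5p arms were each positive, from 0.22 for miR-98-5p to 0.54 for let-7d-5p. The 3p arms were mixed, from -0.55 for let-7g-3p to 0.22 for let-7b-3p. edgeR called 0 of the let-7 members over all miRNAs tested, with 8 at an unadjusted p under 0.05, and DESeq2 called 4 (let-7a-5p, let-7c-5p, let-7d-5p and let-7f-5p). In edgeR adjusted over the list alone 6 were called, all higher, among them let-7f-5p at 15565 ± 1721 CPM in knockouts (SD, n = 4) and 10984 ± 767.2 CPM in wild types (SD, n = 3), let-7c-5p and let-7a-5p. The fry rotation test, which tests each list against no change and not against other miRNAs, gave an adjusted p of 0.022 for each of these 3 lists. The let-7 list call was lost with an estimated correlation (adjusted p = 0.22 with an estimated correlation), with the 4 libraries of consecutive title numbers (0.16), without knockout replicate 3 (0.052) or 4 (0.069), and without wild type replicate 2 (0.16) or 3 (0.092).

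**Figure D3:**
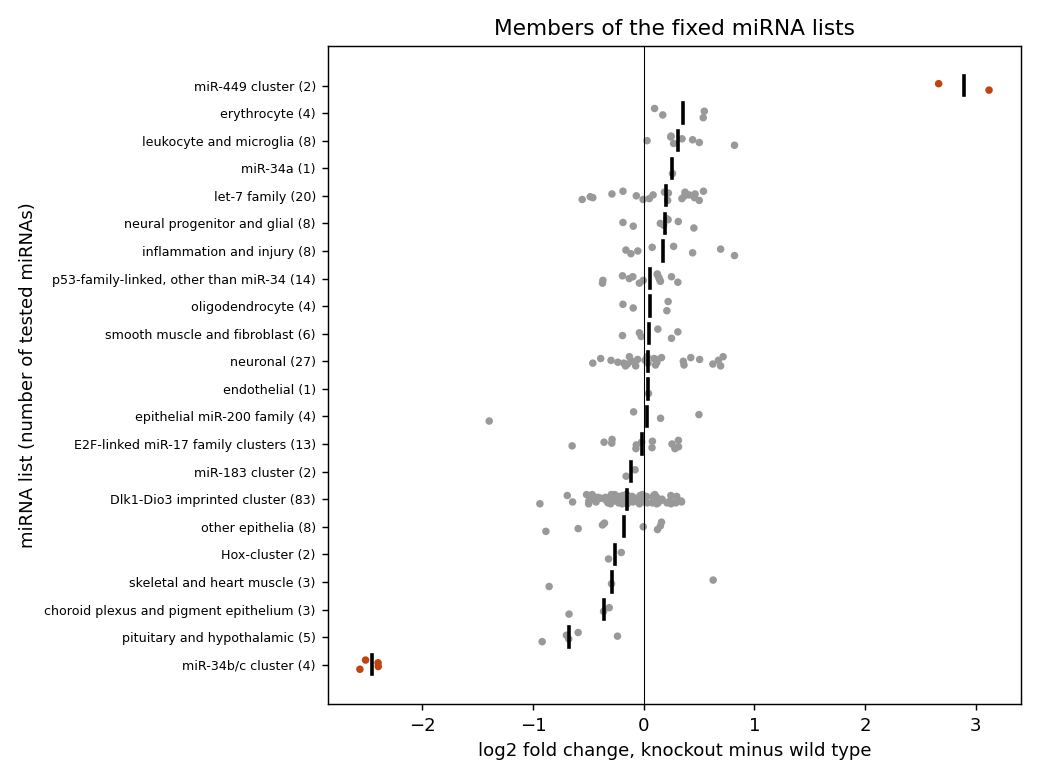
Log2 fold change (knockout minus wild type, horizontal axis) of each tested member of the fixed lists, 1 list per line with its number of tested members. Points are miRNAs, those with an adjusted p under 0.05 over all miRNAs are in orange, and black bars are list medians. The miR-449 members lie at 2.67 and 3.12, the miR-34b/c members between -2.56 and -2.40, and the other list medians between -0.68 and 0.36.

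Lists marking the cell types of the dissected tissue did not pass. The choroid plexus and pigment epithelium list had a median of -0.36, with 3 of 3 members negative (camera adjusted p = 0.69). This median rested on single libraries, at -0.80 without wild type replicate 2 and -0.01 without wild type replicate 3. In it miR-204-5p was at -0.36 ± 0.65, miR-204-3p at -0.67 ± 0.49 and miR-211-5p at -0.31 ± 0.41. The neuronal list had a median of 0.04, with 16 of 27 positive (adjusted p = 0.17). It passed without wild type replicate 2 (adjusted p = 0.014) and with no filter (0.037), and had an adjusted p = 0.75 with an estimated correlation. Its smallest p-values belonged to miR-128-3p (0.70 ± 0.20, edgeR adjusted p = 0.15), miR-132-3p (0.51 ± 0.17, adjusted p = 0.27) and miR-129-2-3p (-0.46 ± 0.17, adjusted p = 0.35). The neural progenitor and glial list had a median of 0.20 (adjusted p = 0.24), with miR-92b-3p at 0.45 ± 0.18 and miR-9-5p at 0.31 ± 0.13. The oligodendrocyte list had a median of 0.06 (adjusted p = 0.89), with miR-338-5p at 0.21 ± 0.17 and miR-338-3p at -0.19 ± 0.26. The neuronal and oligodendrocyte medians were below 0 with library totals alone (-0.04 and -0.03). In these 4 lists the main edgeR test called 0 members over all miRNAs or adjusted over the list alone, DESeq2 called 0, and 6 neuronal and 2 glial members had an unadjusted edgeR p under 0.05. Without wild type replicate 2, edgeR called 3 neuronal members (miR-128-3p, miR-132-3p and miR-212-3p), with no filter 3 and with the miR-204 and miR-211 covariate 1, miR-128-3p. With the 4 libraries of consecutive title numbers it called miR-92b-3p (adjusted p = 0.031). When knockout replicate 3 and wild type replicate 2 were left out together, a choice made after seeing the data, it called 4 neuronal members.

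Blood and vessel lists also missed the threshold. All 8 tested leukocyte and microglia members were positive, with a median of 0.31 (camera adjusted p = 0.051), among them miR-223-3p at 0.82 ± 0.40 and miR-150-5p at 0.35 ± 0.18. This list passed without knockout replicate 1 (adjusted p = 0.024) or wild type replicate 1 (0.037), with library totals alone (0.042), with no filter (0.036) and in the fry test (0.022), and it had an adjusted p = 0.22 with an estimated correlation. The erythrocyte list had a median of 0.36, with 4 of 4 positive (adjusted p = 0.11), with miR-144-3p at 0.54 ± 0.24 and miR-144-5p at 0.55 ± 0.27. It passed without knockout replicate 1 (0.047), with an adjusted p = 0.53 with an estimated correlation. Its median fell to 0.21 without knockout replicate 3. The endothelial list had 1 tested member, miR-126a-3p, at 0.04 ± 0.13 (-0.04 with library totals alone). The smooth muscle and fibroblast list had a median of 0.05, or -0.03 with library totals alone (adjusted p = 0.72), with miR-145a-3p at 0.25 ± 0.19 and miR-143-5p at 0.31 ± 0.42. The inflammation and injury list had a median of 0.17 (adjusted p = 0.51), with miR-223-3p and miR-210-5p (0.70 ± 0.43).

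Of the epithelial lists, the miR-200 family had a median of 0.03 (-0.05 with library totals alone) and a mean of -0.21, so that these differed in sign (camera adjusted p = 0.99, direction up). Within it miR-141-3p was at -1.39 ± 0.44 and was lower when adjusted over the list alone (edgeR adjusted p = 0.035) but not over all miRNAs (0.23, or 0.0065 with no filter), and its wild type level of 25.4 ± 21.5 CPM (SD, n = 3) included 50.1 CPM in wild type replicate 3. miR-429-3p was at 0.50 ± 0.26. The miR-183 cluster had a median of -0.12 (adjusted p = 0.72), with miR-182-5p at -0.16 ± 0.16 and miR-183-5p at -0.08 ± 0.25. The other epithelia list had a median of -0.18 (adjusted p = 0.72), with miR-205-5p at -0.88 ± 0.37 and miR-215-5p at -0.37 ± 0.26.

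Lists for neighbouring brain regions and other tissues gave a similar picture. The pituitary and hypothalamic list had a median of -0.68 with 5 of 5 negative (camera adjusted p = 0.062), with miR-7a-5p at -0.92 ± 0.32 and miR-7b-5p at -0.70 ± 0.32. It passed without wild type replicate 1 (0.0021) or knockout replicate 1 (0.047) and with no filter (0.036), with an adjusted p = 0.44 with an estimated correlation. Its median rested on single libraries, at -0.98 without wild type replicate 1 and -0.30 without wild type replicate 3. In wild type replicate 3 miR-7a-5p stood at 343.1 CPM, against 121.5 and 158.1 CPM in wild type replicates 1 and 2. In the imprinted Dlk1-Dio3 cluster 59 of 83 members were negative, with a median of -0.15 (adjusted p = 0.062), led by miR-758-3p at -0.94 ± 0.32 (called by edgeR with no filter only, adjusted p = 0.027) and miR-380-3p at -0.41 ± 0.15. This cluster list passed without wild type replicate 1 (0.016), without knockout replicate 1 (0.044) and with library totals alone (0.043), with an adjusted p = 0.44 with an estimated correlation. Its leading member miR-758-3p stood at 226.0 CPM in wild type replicate 3, against 103.8 and 73.5 CPM in wild type replicates 1 and 2. The Hox-cluster list had a median of -0.26 (adjusted p = 0.43), with miR-10b-5p at -0.32 ± 0.18 and miR-10a-5p at -0.20 ± 0.15. The skeletal and heart muscle list had a median of -0.29 (adjusted p = 0.72), with miR-133a-3p at -0.85 ± 0.33 and miR-208a-5p at 0.63 ± 0.40.

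Lists linked to the p53 family and to the cell cycle did not stand apart. The p53-family-linked miRNAs other than miR-34 had a median of 0.06 (-0.01 with library totals alone), with 7 of 14 positive (camera adjusted p = 0.72), with miR-215-5p at -0.37 ± 0.26 and miR-145a-3p at 0.25 ± 0.19. The E2F-linked clusters of the miR-17 family had a median of -0.02 and a mean of -0.03 while the test leaned up (adjusted p = 0.99), with miR-92a-3p at 0.28 ± 0.14 and miR-17-5p at -0.36 ± 0.22. In both, 0 members were called by edgeR over all miRNAs or adjusted over the list alone, 0 had an unadjusted p under 0.05, and DESeq2 called 0.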

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

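Of the explanations weighed here, the thinning (chosen after the data were seen) and the count over other groupings of the libraries were specified before their own results were seen, and the choroid plexus, read-sharing and cell share tests after.

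Among the 4 knockout libraries, 73 values were examined for a sample far from the others and 3 stood out, where chance alone gives about 1 in 20. The share of rRNA gene reads was 0.0175% in knockout replicate 2 and 0.0144% to 0.0145% in the other 3, a gap of 0.977 of the group's range. miR-34b-3p was 6.39 CPM, from 6 reads, in knockout replicate 3 and 8.50 to 8.73 CPM in the others, a gap of 0.914 of the range on the log2 scale. miR-208a-5p was 1.07 CPM, from 1 read, in knockout replicate 3 and 5.16 to 6.07 CPM in the others, a gap of 0.897 of the range. The 3 wild type libraries were too few for this examination.

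The main pattern was the opposite movement of the miR-449 and miR-34b/c clusters. With the covariate made of miR-204 and miR-211, 6 of the 6 called arms still passed. This argues against a different share of choroid plexus in the dissections only as far as the covariate tracks that share. Its arms count equally, and miR-204-3p and miR-211-5p were low, at means of 2.63 and 4.62 CPM in knockouts. In wild types they stood at 4.38 and 4.72 CPM, so part of such a difference could remain after adjustment. Uneven depth was argued against by thinning every library to 955057 mouse miRNA reads, after which 6 of 6 also passed. Reads of miR-34b/c counted as miR-449 would keep the sum of both clusters level, but the sum changed by -1.96 on the log2 scale, which argues against this as the account of the miR-34b/c fall, and a fixed share of miscounted reads would lower miR-449 along with miR-34b/c, while the miR-449 sum rose by 2.71 in edgeR. A different share of multiciliated cells, if they are the source of both clusters, would leave the ratio of miR-449 to miR-34b/c level, but the log2 ratio was 4.85 higher in the knockouts, which argues against it as the whole account. The -1.96, the 2.71 and the 4.85 restate the changes of both clusters already given, which these explanations forbid in size or direction. They are no separate evidence for those changes. Chance is an unlikely account of the number of calls. Only 1 of the 35 splits of the 7 libraries, the real one, gave as many as 6, and the highest other gave 2. That share, 0.029, is the smallest that 35 splits allow, so chance is not excluded beyond it. The called arms also belong to the same miR-449 and miR-34b/c clusters and are not independent of each other. An effect of the genotype, a change within the multiciliated cells, an unrecorded batch and a wrong label stay open as untested.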

How the results depend on the processing

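No called miRNA and no list past the threshold changed direction under the alternatives. Medians of lists that did not pass were less stable: 9 of 22 list medians changed sign in at least 1 of 13 settings, among them other epithelia (-0.26 to 0.19), oligodendrocyte (-0.18 to 0.18), smooth muscle (-0.10 to 0.20) and inflammation (-0.04 to 0.26). The 6 called arms kept their sign in all 20 alternatives, with log2 fold changes of 2.73 to 3.52 for miR-449c-5p, 2.43 to 3.13 for miR-449a-5p, -2.84 to -2.33 for miR-34b-3p, -2.73 to -2.10 for miR-34b-5p, -2.72 to -1.90 for miR-34c-5p and -2.83 to -2.10 for miR-34c-3p. miR-34c-3p was also lost with limma-voom (adjusted p = 0.086, range over alternatives 3.9e-10 to 0.16), and miR-34c-5p with no filter (0.12) and with the 4 libraries of consecutive title numbers (0.33, range 3.5e-10 to 0.33). The count of 6 became 14 (8 higher) with DESeq2 and 19 (9 higher, 10 lower) with no filter. Chosen after seeing the data, leaving out knockout replicate 3 and wild type replicate 2 together gave 19 (7 higher, 12 lower), 6 of the 6 main calls among them. The cause was not tested in any of these. Leaving out 1 library at a time gave 3 to 14 calls, 1 to 6 higher and 2 to 8 lower. The log2 difference then ranged from 2.31 to 2.96 for the miR-449 cluster and from -2.76 to -2.05 for the miR-34b/c cluster. With fewer libraries the exact test cannot reach 0.05, so its p-values say nothing there. The edgeR test moved the miR-449 sum past the threshold (2.71). The lists past the threshold numbered 5 with library totals alone, 6 with no filter, and 2 to 7 without 1 library at a time, with the 7 reached without knockout replicate 1. The cause was not tested. Of 1220 further comparisons for 63 named miRNAs, 1190 kept their side of the threshold, 12 lost and 18 gained a call. For 18 other lists, 283 of 304 kept it, 7 lost and 14 gained a call. No paired analysis was possible because the numbers in the titles are not shared between the genotypes. Depth limits low arms: 750 miRNAs with reads were too low to test.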

Other observations

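The host-gene sets, the ratios to miR-204-5p, the shares of the other RNA classes, the test of the other small RNAs and the thinning were chosen after the data were seen, while the scalings, the covariate and the omission of single libraries had been fixed before. Of the 534 tested arms, 484 were matched by name to a hairpin gene. Grouped by the gene that contains their hairpin, they gave 24 sets of at least 3 arms, the largest with 22 (Mirg). Arms with a hairpin in no other gene, or in a gene with fewer arms, were in no set. Some sets, such as those of Gm13648 and Ttll10, had identical values. The 9 arms within Htr2c, the serotonin receptor gene strongly expressed in choroid plexus (chromosome X, 146962513 to 147197277, plus strand, GRCm38), were each negative, with a median log2 fold change of -1.04 (camera adjusted p = 7.9e-05, and adjusted p = 0.78 with an estimated correlation). The median was -0.50 with the 4 libraries of consecutive title numbers. edgeR called 0 of the 9, 4 had an unadjusted p under 0.05, and DESeq2 called 1, miR-1298-3p. edgeR also called miR-1298-3p with no filter and without wild type replicate 2, and it called 4 of the 9 (miR-1298-3p, miR-1298-5p, miR-1912-3p and miR-448-3p) when knockout replicate 3 and wild type replicate 2 were left out together. The arms named next were chosen after their values were seen. miR-1298-3p stood at 138.7 ± 22.9 CPM in knockouts (SD, n = 4) and 240.5 ± 55.1 CPM in wild types (SD, n = 3), at -0.78 ± 0.20 (edgeR adjusted p = 0.10). miR-764-5p was at -1.52 ± 0.41 and miR-448-3p at -1.04 ± 0.57. The 4 arms of miR-132 and miR-212, neuronal miRNAs induced by activity, lie in the transcript 1700016P03Rik and had a median of 0.40 (camera adjusted p = 0.045, and adjusted p = 0.78 with an estimated correlation).

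The hypothesis that the Htr2c miRNAs are lower in the knockout was then examined. With the miR-204 and miR-211 covariate the median moved from -1.04 to -0.58 (camera adjusted p = 0.0026 at the preset correlation, and adjusted p = 0.68 with an estimated correlation). A different share of choroid plexus therefore stays open, since this median ran from -0.81 to -0.38 without 1 library at a time (jackknife standard error 0.29) and so did not clear the bound of -0.5 by more than its spread. A single library as the whole account is argued against, since the median stayed between -1.47 and -0.66 without 1 library at a time. The highest camera adjusted p was then 0.015, which met the bound written before. This p is at the preset correlation, where other splits reach p-values as small, so it does not bear on chance. Chance could not be excluded: 9 of the 35 splits gave a host-gene set with as small a p, the real smallest being 3.3e-06 and the smallest in another split 1.9e-12. Those splits point to a structure of the samples that camera with its preset correlation does not allow for, and the hypothesis may rest on it. miR-1298-5p ranged from 184.4 to 785.3 CPM within the knockouts and from 299.3 to 1992 CPM within the wild types, and it was lowest in knockout replicate 3 and wild type replicate 2, the libraries lowest in miR-204-5p.

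For let-7, thinning left the list median at 0.27, against 0.20 before thinning, with a camera p of 0.0020 before adjustment. This met the bound written before. Thinning left 411 miRNAs tested, against 534 before, so the 2 medians need not cover the same let-7 members. The step from 0.20 to 0.27 is therefore not read as a gain. For the members still tested, the positive median argues against uneven numbers of reads as the account of the let-7 rise. The camera p does not bear on chance, since other splits reach p-values as small at this preset correlation as the real one. Over 4 scalings the let-7 median was lowest with library totals alone, at 0.12, where the median of all tested miRNAs was -0.10. Each of these scalings moves all miRNAs together, by at most -0.08 here, and cannot set let-7 apart from the others. The gap between let-7 and the other miRNAs was thus largely fixed beforehand. These scalings therefore cannot decide whether scaling accounts for the list call. A scaling that depends on the level of a miRNA was not tried. Chance could not be excluded, since 3 of the 35 splits gave as small a p (0.0045 for the real split, 9.4e-04 for the smallest of the others). The same holds for the number of lists past the threshold, where 9 of the 35 splits gave at least the real 3 and the highest other gave 8. No biological explanation was tested for let-7.

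Set against the choroid plexus miRNA miR-204-5p, the miR-449 cluster was nearly constant across the knockouts, at 28.3, 24.5, 27.7 and 30.1 reads per 1000 miR-204-5p reads in replicates 1 to 4, although miR-204-5p itself ran from 2042 to 7674 CPM. The wild types had 2.32, 15.5 and 1.93. The means were 27.6 ± 2.31 in knockouts (SD, n = 4) and 6.59 ± 7.74 in wild types (SD, n = 3; exact permutation p = 0.029, adjusted p = 0.048 over 5 such comparisons). The miR-34b/c cluster had 104.0 ± 41.7 reads per 1000 in knockouts (SD, n = 4) and 442.6 ± 164.6 in wild types (SD, n = 3; exact permutation p = 0.029, adjusted p = 0.048). These p-values are the smallest possible, and the ratios were chosen after both clusters had been seen to separate the groups. The 5 comparisons also included the miR-449 share of the reads of both clusters, which repeats that separation. The ratios are therefore no separate evidence for it. The neuronal miR-124-3p stood at 8125 ± 1668 CPM in knockouts (SD, n = 4) and 7261 ± 2026 CPM in wild types (SD, n = 3; exact permutation p = 0.57).

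Outside mouse miRNAs, edgeR tested 169 small RNAs and called 0, with 7 (4.14%) at an unadjusted p under 0.05, and DESeq2 called 0. The smallest p-values belonged to a predicted miRNA and to the snoRNA Snord99, named after its value was seen, at -1.11 ± 0.37 (edgeR adjusted p = 0.85). piRNA rows held 0.932% ± 0.178 of reads in knockouts (SD, n = 4) and 0.880% ± 0.081 in wild types (SD, n = 3; exact permutation p = 0.86). Rows of other species held 0.0059% ± 0.0002 in knockouts (SD, n = 4) and 0.0069% ± 0.0005 in wild types (SD, n = 3; exact permutation p = 0.029, the smallest possible, before adjustment over the 10 depth and class comparisons).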
